A study of Mus musculus with 12 samples.

How the data were processed

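The samples were 12 arrays of RNA from cells of postnatal day 7 mouse spinal cord, 3 biological replicates in each of 4 groups formed by region (dorsal, ventral) and sort (Aldh1l1-GFP positive astrocytes, GFP-negative non-astrocytes). Per the labels' protocols, cords of Aldh1l1-GFP mice on a Swiss-Webster background were dissociated with papain and flow sorted, and the RNA was purified with Trizol, DNase digested, amplified and labelled with biotin. Per the submitters' processing notes, oligo, RMA and limma were used, and their versions and order are not given in the sources used here. The deposited series table by the authors holds RMA values per probe set on a log2 scale, background corrected, quantile normalized and summarized over the 12 arrays. The authors' 2 further tables, of astrocytes against non-astrocytes and of dorsal against ventral astrocytes, give per listed probe set a gene name, the same log2 values, a fold change as a linear ratio, a t statistic score of limma, a p-value and an adjusted p-value. These tables by the authors hold 5158 and 39 entries, for 5109 and 39 distinct probe sets, all with an adjusted p-value up to 0.15 and 0.14, and their p-values imply that 7799 features were tested by the authors. The genome build is not given in the sources used here, so no coordinates are printed.

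The series table held 35556 probe sets, of which 476 repeated the values of another in all arrays and were collapsed, leaving 35080. No table used here pairs probe set identifiers with genes. Names were therefore taken from the authors' tables, by an exact match of the 12 values to 6 decimals. All 5158 and all 39 listed entries matched. This named 5116 probe sets of 4575 genes, and 3 probe sets with conflicting names were left unnamed. Names were updated through the RefSeq table of assembly GRCm38.p6, in which 4327 and 34 of the listed names were symbols, 641 and 5 synonyms, and 190 and 0 were not found. Because nearly all names come from the authors' table of astrocytes against non-astrocytes, the named genes were selected on that comparison, and those from the table of dorsal against ventral astrocytes on that one; list tests use the named genes as their background. The identifiers of the first 6613 probe sets run one by one, unlike the others, and none of them has a name. They were left out as control-type probe sets, on the numbering alone, and 28467 probe sets were tested. This was settled after both counts of the dorsal against ventral astrocyte comparison had been seen, 97 without the block and 46 with it, so both are given.

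The design was written for genes, with the fallback that probe sets are tested as such where the files pair none with genes, and that fallback applied. The 4 comparisons, their tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Each comparison was a contrast of limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group over all 12 arrays, 8 residual degrees of freedom and 4.59 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over the probe sets and a threshold of 0.05. The contrasts were dorsal against ventral astrocytes, the mean of both astrocyte groups against the mean of both other groups, dorsal against ventral non-astrocytes, and the difference of both regional contrasts. Standard errors are those of the moderated test of limma, except that of 1 median over astrocyte markers, described where it is given. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

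Of 27 gene lists written beforehand, with 472 genes, 231 genes were measured under a name. The 19 lists with at least 5 measured genes were tested with camera of limma with a preset correlation of 0.01 on the brightest probe set of each gene, adjusted over the lists, and again with an estimated correlation and with fry. The other 8 lists had too few, and the list of sex-linked genes had 0 measured under a name. Named genes were, for each comparison and direction, the 10 of largest change among those called whose groups did not overlap (not asked of the interaction), leaving out predicted genes, RIKEN clones, small RNAs and receptor families; per list, up to 4 called members of largest change or, with none called, the 2 of lowest p; and Aldh1l1, Gfap, Aqp4, Slc1a3, Kcnj10 and Sema3a throughout. Members named because they passed when adjusted over the list alone were chosen after their values were seen.

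The labels give the groups equal replicate numbers without saying what these share, so the main fit has no block. In the authors' tables the columns of the 4 arrays of each replicate carry a common number, 3, 5 and 8 for replicates 1, 2 and 3. In the pairing check, the deviations from the group means of same-numbered arrays were correlated across probe sets. The correlations of same-numbered dorsal and ventral non-astrocytes were 0.15 to 0.21, against -0.14 to -0.042 for other numbers, so that the numbers pair these arrays by the rule of more than 0.1 in every pair, and the blocked value is given beside that comparison. Those of dorsal and ventral astrocytes were 0.041 to 0.14, against -0.10 to 0.034 for other numbers. They lay above the others but did not meet the rule, so a weaker pairing of the astrocyte arrays stays open. Between ventral astrocytes and ventral non-astrocytes they were 0.086 to 0.12, against -0.10 to -0.017 for other numbers. Every same-numbered correlation in any pair of groups was positive, so a pairing across all 4 groups stays open as well. The alternatives were a replicate block, other normalizations between arrays, a filter on dim probe sets, other treatments of probe sets per gene, a trended and robust prior, array weights, stricter thresholds, separate fits and leaving out arrays. The fit was tested on simulated data of the dorsal against ventral astrocyte comparison with 28467 probe sets and 50 changed per size. It recovered 46% of changes of 0.5 on the log2 scale, 90% of 1 and 100% of 1.5 and of 2, with 5 false calls among 173, and a list shifted by 0.5 was called with no other list called among 19. The simulated noise was independent between probe sets and equally wide in all groups, without pairing of replicates. The real arrays differ in this, so these rates may be too favourable for them.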

Results

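RNA was measured on 12 arrays from postnatal day 7 mouse spinal cord, taken from its dorsal or its ventral part. Cells from mice carrying the Aldh1l1-GFP transgene, in which green fluorescent protein marks astrocytes, were sorted into GFP-positive astrocytes and GFP-negative cells, called non-astrocytes here. The 4 groups were dorsal astrocytes, ventral astrocytes, dorsal non-astrocytes and ventral non-astrocytes, with 3 biological replicates each. The median log2 signal of an array lay between 6.57 and 6.62 over the 28467 probe sets tested, and the number of arrays limits the precision. The first principal component held 69.5% of the variance and separated the 6 astrocyte arrays from the 6 non-astrocyte arrays. Gene names were known for 5116 of the probe sets, which covered 4575 genes.

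The comparison of astrocytes with non-astrocytes asked which transcripts set the sorted GFP-positive population apart from the remaining cells of the cord. The zinc transporter gene Slc39a12 was 46.7-fold higher in astrocytes, with a log2 signal of 10.74 ± 0.28 in astrocytes and 5.20 ± 0.28 in non-astrocytes (SD, n = 6 each). The water channel gene Aqp4 was 34.1-fold higher, at 11.63 ± 0.10 against 6.54 ± 0.39 (SD, n = 6 each), and Aldh1l1, whose promoter drives the sorting marker, was 12.1-fold higher, at 9.49 ± 0.31 against 5.89 ± 0.12. In the other direction, the haemoglobin gene Hba-a1 was 14.8-fold higher in non-astrocytes, at 11.81 ± 0.09 against 7.92 ± 0.40, and Mog, which encodes a surface protein of myelin, was 6.83-fold higher, at 10.75 ± 0.31 against 7.98 ± 0.23 (SD, n = 6 each).

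With limma, 10305 of 28467 probe sets passed an adjusted p of 0.05, of which 4698 were higher in astrocytes and 5607 higher in non-astrocytes. At least 2-fold differences were found for 1014 and 766 of these. The 10 named genes furthest above non-astrocytes were Slc39a12, Htra1, Slc6a11, Aqp4, Slc4a4, Elovl2, Ttpa, Pla2g7, Atp13a4 and Ppp1r3c, with log2 fold changes from 5.55 (SE 0.13) for Slc39a12 to 4.52 (SE 0.12) for Ppp1r3c. Among them, Slc6a11 encodes a GABA transporter, at 5.23 (SE 0.13), and Elovl2 an enzyme that lengthens polyunsaturated fatty acids, at 4.99 (SE 0.13). The 10 furthest below were Hba-a1, Il1a, Hbb-b1, C3ar1, Ermn, Rgs5, Ppp1r14a, Klhl4, Ctss and Cd53, from -3.89 (SE 0.13) for Hba-a1 to -2.89 (SE 0.14) for Cd53. They included the cytokine gene Il1a at -3.55 (SE 0.30) and the pericyte gene Rgs5 at -3.14 (SE 0.34). By the rule of naming, each of these 20 genes had all 6 values of one population above all 6 of the other, and its adjusted p in limma was at most 7.9e-06. Gfap, which encodes the intermediate filament of astrocytes, had a log2 fold change of 3.95 (SE 0.20), the glutamate transporter gene Slc1a3 3.72 (SE 0.06), the potassium channel gene Kcnj10 1.83 (SE 0.07) and the guidance gene Sema3a 1.28 (SE 0.15). For Sema3a this is a mean of unequal regional values, with 2.40 between the ventral populations and 0.17 between the dorsal ones, where it was not called (adjusted p = 0.63).

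Of the 19 tested gene lists, fixed beforehand, camera called 8, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). Names came almost wholly from the authors' own table of this comparison, so the number of list members passing the test is not independent evidence. Adjusting over the list alone changed it in only 2 lists, and the list tests compare directions among genes selected that way. All 19 measured astrocyte markers were higher in astrocytes (median 3.60, camera adjusted p = 2.9e-08 in limma, 0.097 as adjusted p with an estimated correlation), among them Mlc1 at 4.28 and Gjb6 at 4.24. All 20 astrocyte transporter and channel genes were higher as well (median 3.76, adjusted p = 2.9e-09, and adjusted p = 0.15 with an estimated correlation). All 13 measured markers of myelinating oligodendrocytes were lower in astrocytes (median -2.31, adjusted p = 1.8e-05, and adjusted p = 0.25 with an estimated correlation), with Opalin at -2.83, Mog at -2.77 and Mag at -2.67. The 9 oligodendrocyte precursor markers were lower (median -1.22, adjusted p = 0.0018, and adjusted p = 0.18 with an estimated correlation), led by Pdgfra, a growth factor receptor gene, at -2.59 and Gpr17 at -2.39. The 13 microglia markers were lower (median -2.16, adjusted p = 0.00018, and adjusted p = 0.29 with an estimated correlation), with Ctss at -2.95, Tyrobp at -2.67 and Csf1r at -2.33. The 20 cell proliferation genes were lower too (median -1.09, adjusted p = 0.00036, and adjusted p = 0.43 with an estimated correlation), including Top2a at -2.06 and Mki67 at -1.72.

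Of the signalling lists, 15 of 15 measured Hox genes, which mark position along the body axis, were higher in astrocytes (median 0.77, adjusted p = 0.0027, and adjusted p = 0.11 with an estimated correlation), with Hoxc8 at 2.31 and Hoxb5 at 1.32. All 5 measured genes of the neurotrophic factor list were higher (median 0.77, adjusted p = 0.043, and adjusted p = 0.21 with an estimated correlation). The largest change, 2.99, was that of Ednrb, which encodes an endothelin receptor and not a factor, and Vegfa stood at 1.34. The list was not tested without Ednrb. Its call was lost without the arrays of replicate 2 (adjusted p = 0.053). The remaining 11 tested lists were not called by camera. In the Sonic hedgehog list, 7 of 9 genes were higher and 2 lower (adjusted p = 0.079), with the transcription factor gene Gli3 at 2.22 and the receptor gene Ptch1 at 2.09. Above the median signal this list was called (adjusted p = 0.027). Astrocyte synapse-regulating factors had 10 of 14 higher and 4 lower (adjusted p = 0.094), with the glypican genes Gpc5 at 3.14 and Gpc4 at 2.57. The Wnt and BMP list had 7 of 10 higher and 3 lower (adjusted p = 0.23), with Id3 at 2.72 and Bmp4 at -1.97. Pan-neuronal markers had 2 of 8 higher and 6 lower (adjusted p = 0.15). The 2 higher were the neurofilament genes Nefl at 0.93 and Nefm at 0.78, and Dcx, a gene of young neurons, was lower at -2.17. Endothelial markers had 1 of 8 higher and 7 lower (adjusted p = 0.17), and mural and fibroblast markers 1 of 5 higher and 4 lower (adjusted p = 0.27).

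Semaphorins, neuropilins and plexins divided into 8 higher and 10 lower of 18 (adjusted p = 0.69), with Sema4b at 1.73 and Sema3d at -2.32. Ephrin, slit, netrin and draxin genes divided 7 and 7 of 14 (adjusted p = 0.97), with Robo2 at 1.76 and Ephb1 at -1.93, and here camera pointed up while the median (-0.07) and the mean (-0.03) were negative. Extracellular matrix genes divided 6 and 7 of 13 (adjusted p = 0.80), with Tnc at 3.44, Hapln1 at 3.15 and Tnr at -2.26, and the median was -0.43 while the mean (0.30) and the test pointed up. Dorsal progenitor patterning genes had 4 of 5 higher (adjusted p = 0.27), with Zic1 at 1.15 (1.78 within the dorsal part and 0.53 within the ventral) and Pax3 at 1.11 (1.59 and 0.63). Of the immediate early and heat shock genes, 2 of 6 were higher and 3 lower, with Fos at 1.37 and Ier3 at -1.07 (adjusted p = 0.72), and 6 passed when adjusted over the list alone. Egr2 of this list, at -0.70, was called with adjusted p = 0.035 and lost its call without any 1 of 8 arrays, with adjusted p up to 0.085. These were dorsal and ventral astrocytes 1, dorsal and ventral astrocytes 3, dorsal and ventral non-astrocytes 1, and ventral non-astrocytes 2 and 3. It did not pass within the ventral part alone either (-0.40, adjusted p = 0.45). The test fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, called 17 of 19 lists. Lists with fewer than 5 measured genes were not tested as lists. All 4 measured red blood cell genes were lower in astrocytes (median -2.11). The ventral patterning list had Pax6 (2.00) and Dbx2 (1.44) higher and Nkx2-2 (-0.91) and Olig2 (-0.45) lower. Rorb (2.88) and Reln (2.88, from 2.17 dorsally and 3.59 ventrally) of the dorsal horn list were higher and Tac1 (-2.24) lower. Ret (0.47), Esrrg (0.79) and Rarres2 (0.51) were higher as the lone measured members of the motor neuron, ventral interneuron and ependymal lists. Within the dorsal part alone, Ret (0.17, adjusted p = 0.35) and Rarres2 (0.38, adjusted p = 0.23) did not pass, against 0.76 and 0.64 within the ventral part. Cdh19 (0.66, adjusted p = 0.081), the lone measured Schwann and ganglion marker, did not pass over all probe sets and passed when adjusted over the list alone.

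**Figure D1:**
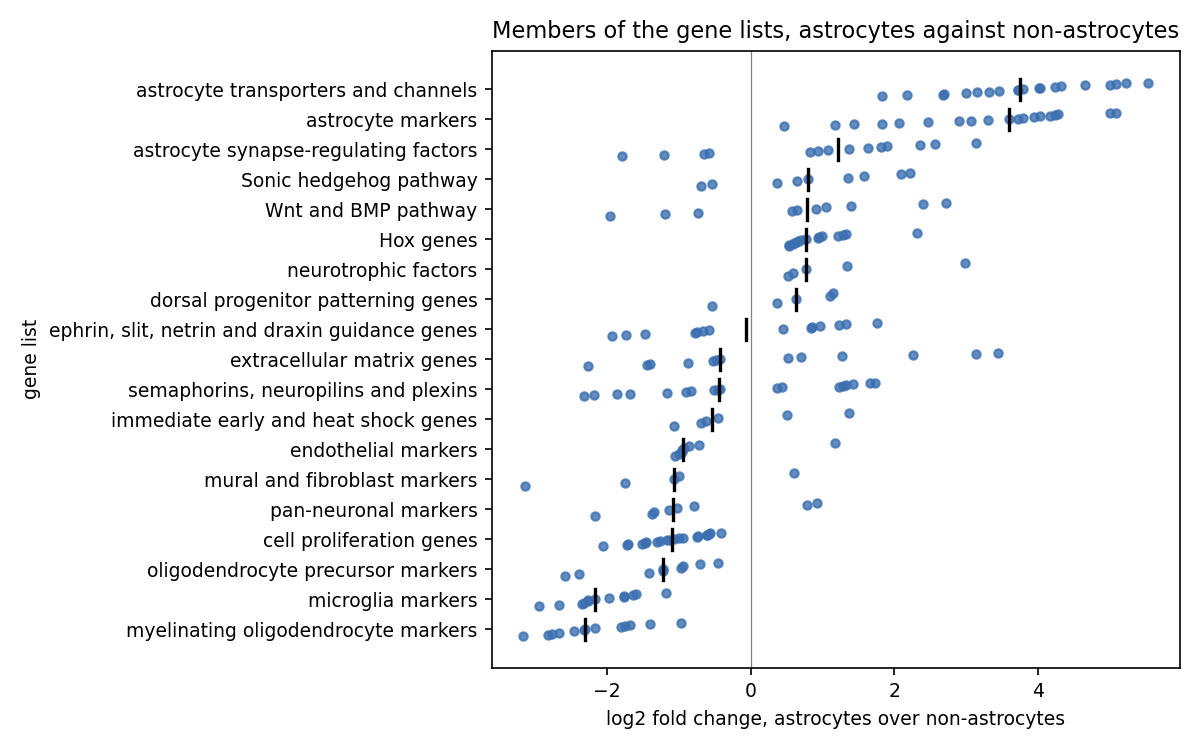
Log2 fold change of astrocytes over non-astrocytes (horizontal axis) for each measured member (points) of the 19 gene lists tested (vertical axis), with the list median as a bar. The astrocyte lists sit to the right, with medians of 3.76 and 3.60, and the myelin and microglia lists to the left, with medians of -2.31 and -2.16.

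The comparison of dorsal with ventral astrocytes asked whether astrocytes carry transcripts that mark their position in the cord, the subject named in the title of the study. Ventral astrocytes had 4.92-fold more signal for Sema3a, which encodes a secreted repellent of growing axons, at 8.11 ± 0.40 against 5.81 ± 0.38 in dorsal astrocytes (SD, n = 3 each). They had 3.36-fold more for Epha5, an ephrin receptor gene, at 8.98 ± 0.19 against 7.24 ± 0.19 (SD, n = 3 each). Dorsal astrocytes had 3.76-fold more signal for Hs3st3a1, which encodes an enzyme that modifies heparan sulfate, at 8.45 ± 0.09 against 6.54 ± 0.32 (SD, n = 3 each). Dorsal patterning transcription factors were among the dorsal genes, with Zic1 2.98-fold higher, at 8.63 ± 0.18 against 7.05 ± 0.22, and Pax3 2.50-fold higher, at 8.25 ± 0.14 against 6.93 ± 0.38 (SD, n = 3 each).

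In limma, 97 probe sets differed between dorsal and ventral astrocytes, 38 higher dorsally and 59 higher ventrally, and 44 differed at least 2-fold. Of the 97, 62 had names and stood for 60 genes. All 97 had every dorsal value on one side of every ventral value. Chance gives such a separation to 10% of probe sets, but these 97 were called on the same values, so it is no further support. The 10 named genes furthest to the dorsal side, as log2 fold change of dorsal over ventral, were Hs3st3a1 at 1.91 (SE 0.16, adjusted p = 0.00027), Unc13c at 1.59 (SE 0.12), Zic1 at 1.58 (SE 0.16), Slc30a10 at 1.50 (SE 0.16), Trhr at 1.45 (SE 0.24), Cyp4f15 at 1.41 (SE 0.16), Pax3 at 1.32 (SE 0.17), Pamr1 at 1.22 (SE 0.22), Hapln1 at 1.20 (SE 0.14) and Sez6l at 1.15 (SE 0.16). A second probe set of Unc13c was called at 0.81 (SE 0.13). Unc13c belongs to a family that primes synaptic vesicles, Slc30a10 encodes a manganese exporter, Trhr a receptor for thyrotropin-releasing hormone, and Hapln1 a protein that links hyaluronan to proteoglycans. The 10 furthest to the ventral side were Fads2b at -3.45 (SE 0.36), Sema3a at -2.30 (SE 0.21, adjusted p = 0.00042), Lix1 at -2.01 (SE 0.31), Gpr37 at -1.87 (SE 0.16), Epha5 at -1.75 (SE 0.14, adjusted p = 0.00020), Fgf7 at -1.68 (SE 0.31), Dnah12 at -1.49 (SE 0.21), Padi2 at -1.43 (SE 0.23), Fmod at -1.39 (SE 0.15) and Bgn at -1.38 (SE 0.19). Fads2b stood at 7.92 ± 0.99 in ventral and 4.47 ± 0.19 in dorsal astrocytes (SD, n = 3 each). The dorsal value lay well under the array medians of 6.57 to 6.62, so the size of its change is uncertain. The dorsal value of Sema3a, 5.81, lay under these medians too, so the size of its change is also less certain. Fmod and Bgn encode small leucine-rich proteoglycans of the extracellular matrix, Fgf7 a fibroblast growth factor and Dnah12 a dynein heavy chain of motile cilia. The general astrocyte genes did not pass: Aldh1l1 stood at 0.33 (SE 0.16), Gfap at -0.59 (SE 0.28), Aqp4 at 0.05 (SE 0.20), Slc1a3 at -0.21 (SE 0.08) and Kcnj10 at 0.00 (SE 0.10).

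Of the 20 genes of largest change, 14, with Sema3a, Epha5, Hs3st3a1, Zic1 and Pax3 among them, stayed called whichever of the 6 astrocyte arrays was left out. Over the alternatives at this threshold, Sema3a was called in 19 of 19 and Epha5 in 20 of 20. Hs3st3a1 was called in 18 of 19, Zic1 in 19 of 20 and Pax3 in 18 of 20 (adjusted p up to 0.056, 0.052 and 0.25 in limma). Dnah12 was lost without dorsal astrocytes 1 (adjusted p = 0.057). Fgf7, Lix1 and Padi2 were lost without any 1 of dorsal astrocytes 1 and 2 and ventral astrocytes 2 and 3 (adjusted p up to 0.15, 0.074 and 0.081). Pamr1 and Trhr were lost without any 1 of the 6 arrays (adjusted p up to 0.13 and 0.11). The count of 97 was 46 without dorsal astrocytes 1, 62 without ventral astrocytes 1 and 48 without ventral astrocytes 2. Without all arrays of replicate 1, 2 or 3, the count was 23, 8 and 49. It was 46 when the leading block of unnamed probe sets, left out as control-type probe sets, was tested too, 35 with weights per array and 27 when the fit used the astrocyte arrays alone.

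Among the lists, camera called the dorsal progenitor patterning genes higher dorsally (median 0.20, adjusted p = 0.022, and adjusted p = 0.32 with an estimated correlation), with 2 of 5 measured members, Zic1 and Pax3, higher and the other 3 not passing. Adjusted over the list alone, the count was also 2. The test fry called this list and no other (adjusted p = 0.0034). The myelinating oligodendrocyte markers were called lower dorsally (median -0.29, adjusted p = 0.0090, and adjusted p = 0.54 with an estimated correlation), although 0 of 13 members passed in limma over all probe sets and 1, Mbp at -0.53 (SE 0.11), when adjusted over the list alone. In 12 of the 13 the value was higher ventrally. The call of this list was lost without the arrays of replicate 2 (adjusted p = 0.205). No other list was called over all named genes. Above the median signal, the pan-neuronal (adjusted p = 0.036), precursor (0.043) and ephrin (0.036) lists were called lower and the immediate early list (0.043) higher. Without replicate 3, the first 3 of these were called too (adjusted p = 0.0017, 0.019 and 0.019), and without replicate 2 the immediate early list (0.038). In the ephrin, slit, netrin and draxin list (adjusted p = 0.054, and 0.54 as adjusted p with an estimated correlation), 1 of 14 members, Epha5, passed over all probe sets, and 7 passed when adjusted over the list alone. These were Epha5, Ephb1 (-0.46), Slit2 (-0.47), Dcc (-0.46), Epha7 (-0.37) and Neo1 (-0.33), higher ventrally, and Ephb3 (0.26), higher dorsally. In the semaphorin list (adjusted p = 0.21), 1 of 18, Sema3a, passed, and 2 when adjusted over the list alone, the other being Sema3d at -0.48 (SE 0.12).

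Among the lists not called, pan-neuronal markers had a median of -0.18 (adjusted p = 0.054, and adjusted p = 0.54 with an estimated correlation), with 0 of 8 passing in limma and 3 when adjusted over the list alone (Nefm at -0.85, Nefl at -0.76 and Gap43 at -0.65). Oligodendrocyte precursor markers had a median of -0.17 (adjusted p = 0.054, and adjusted p = 0.54 with an estimated correlation), with 0 of 9 passing and 3 when adjusted over the list alone (C1ql1 at -0.72, Lhfpl3 at -0.44 and Neu4 at -0.37). Immediate early and heat shock genes had a median of 0.38 (adjusted p = 0.054, and adjusted p = 0.66 with an estimated correlation), with 0 of 6 passing and 2 when adjusted over the list alone (Fos at 0.66 and Zfp36 at 0.55). Of the extracellular matrix list, 1 of 13, Hapln1, passed, and 3 when adjusted over the list alone, with Has2 at 0.62 and Tnr at -0.49. Its median (-0.02) was negative while the mean (0.12) and the test (adjusted p = 0.61) pointed up. The astrocyte markers had none of 19 passing by either count, with a median of 0.04, a mean of -0.01 and a test that pointed down (adjusted p = 0.95), and the mural list had a positive median (0.07) and test against a mean of -0.08 (adjusted p = 0.95). Boc (0.45) and Cdon (-0.40) of the hedgehog list (adjusted p = 0.76) and Hoxa2 (0.55) of the Hox list (adjusted p = 0.44) passed only when adjusted over the list alone. Reln, which encodes the extracellular protein reelin and was listed as a dorsal horn neuron marker, was higher ventrally at -1.05 (SE 0.18, adjusted p = 0.029). Its call was lost without dorsal astrocytes 1 or 3 or ventral astrocytes 1 or 2, with adjusted p up to 0.10. Tac1 of the same list was higher dorsally at 1.14 (SE 0.40), and Ret, the measured motor neuron marker, higher ventrally at -0.61 (SE 0.12). Both passed only when adjusted over the list alone (adjusted p = 0.33 and 0.059 over all probe sets).

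The authors' own table of this comparison listed 39 probe sets, 25 of them with an adjusted p under 0.05 in that table. All 39 matched array values used here and were called here, with adjusted p-values that differ from the authors'. In that table Sema3a had a fold of 0.20, dorsal over ventral, and an adjusted p of 0.00042.

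**Figure D2:**
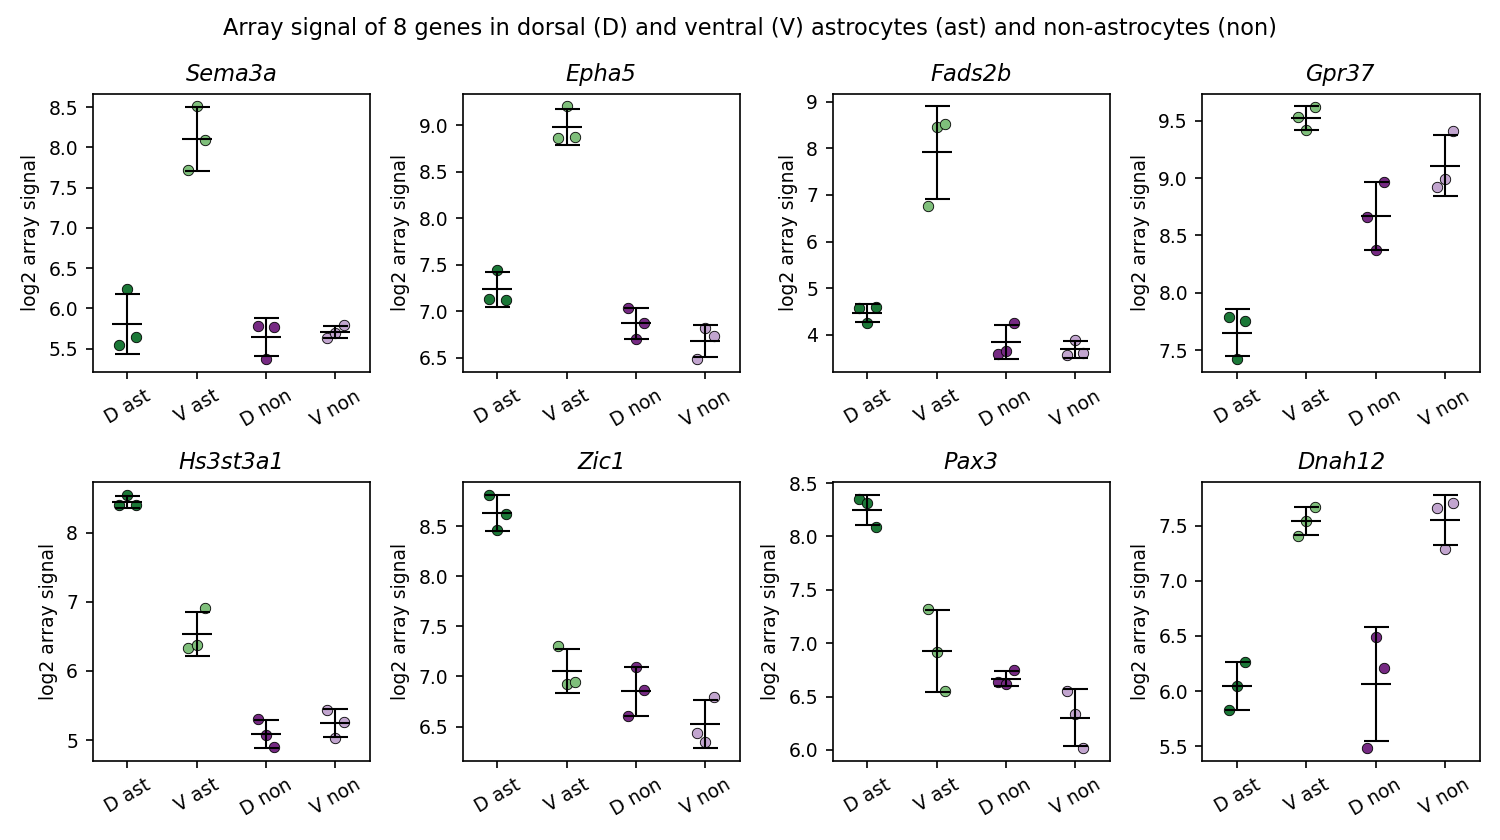
Log2 array signal (vertical axes) of 8 genes in the 12 arrays (points), with the mean and SD of each group of 3 as bars. Sema3a stands at 8.11 in ventral astrocytes and between 5.64 and 5.81 in the other groups, whereas Dnah12 stands near 7.54 and 7.55 in both ventral groups.

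The comparison of dorsal with ventral non-astrocytes asked whether the remaining cells differ by region in the same way. Ventral non-astrocytes had 2.81-fold more signal for Dnah12, at 7.55 ± 0.23 against 6.06 ± 0.52 (SD, n = 3 each), and 1.72-fold more for the urea transporter gene Slc14a1, at 6.74 ± 0.07 against 5.96 ± 0.10 (SD, n = 3 each). Dorsal non-astrocytes had 2.00-fold more for Adgrl2, which encodes an adhesion receptor, at 6.81 ± 0.34 against 5.81 ± 0.16 (SD, n = 3 each). Further genes higher dorsally were Pde7b, a phosphodiesterase gene, at a log2 fold change of 0.79 (SE 0.11), the potassium channel gene Kcnd2 at 0.66 (SE 0.10) and the transcription factor gene Etv5 at 0.58 (SE 0.08).

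These 6 genes were all the named ones among 14 probe sets called, 5 higher dorsally and 9 higher ventrally, each with the dorsal and ventral values apart in all 3 arrays of a group. The same-numbered dorsal and ventral arrays of this population deviated together, and with the replicate number as a block limma called 0 probe sets (1716 at an unadjusted p under 0.05, against 1494 without the block), the adjusted p of the 6 genes being 0.072 to 0.080. The calls also rested on individual arrays: limma called 0 without ventral non-astrocytes 1, 2 or 3 (1363, 1345 and 1254 at an unadjusted p under 0.05), 4 without dorsal non-astrocytes 1, 2 without dorsal non-astrocytes 2 and 31 without dorsal non-astrocytes 3. Limma called 0 as well when the leading block of probe sets was tested too (1698 at an unadjusted p under 0.05). Sema3a stood at -0.07 (SE 0.21), Aldh1l1 at 0.13 (SE 0.16), Gfap at -0.52 (SE 0.28), Aqp4 at -0.35 (SE 0.20), Slc1a3 at -0.03 (SE 0.08) and Kcnj10 at -0.31 (SE 0.10), none of them passing.

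Camera called 6 lists, with and without the block, though with an estimated correlation it called 0 of 19 (1 at an unadjusted p under 0.05) and fry called 0 (4 at an unadjusted p under 0.05). All 13 microglia markers had higher values dorsally (median 0.43, adjusted p = 8.2e-06, and adjusted p = 0.33 with an estimated correlation), with 0 passing in limma over all probe sets and 4 when adjusted over the list alone, namely Laptm5 (0.77), C1qa (0.52), Csf1r (0.51) and C1qb (0.36). All 13 myelin markers had higher values ventrally (median -0.25, adjusted p = 0.00030, and adjusted p = 0.35 with an estimated correlation), with 0 passing by either count and Mog at -0.42. Oligodendrocyte precursor markers were called higher dorsally (median 0.11, adjusted p = 0.020, and adjusted p = 0.33 with an estimated correlation), with 0 of 9 passing and 3 when adjusted over the list alone, namely Pdgfra (0.55), Lhfpl3 (0.36) and Cspg4 (0.34). Astrocyte synapse-regulating factors were called higher dorsally (median 0.19, adjusted p = 0.020, and adjusted p = 0.33 with an estimated correlation), with 0 of 14 passing and 4 when adjusted over the list alone. Of these, Ptx3 (0.44), Sparc (0.34) and Nlgn2 (0.31) were higher and Thbs4 (-0.49) lower. Hox genes were called higher dorsally (median 0.10, adjusted p = 0.020, and adjusted p = 0.33 with an estimated correlation), with 13 of 15 values positive and 0 passing by either count. Astrocyte transporters and channels were called lower dorsally (median -0.05, adjusted p = 0.030, and adjusted p = 0.59 with an estimated correlation), with 1 of 20, Slc14a1, passing and 7 when adjusted over the list alone, among them Slc13a3 (-0.50), Slc4a4 (-0.50) and, with the opposite sign, Slc38a3 (0.44). The astrocyte markers were not called (median -0.01, adjusted p = 0.155, and adjusted p = 0.59 with an estimated correlation), with 0 of 19 passing and 5 when adjusted over the list alone. Of these, Mlc1 (-0.64), Gja1 (-0.51), Slc4a4 (-0.50) and Kcnj10 (-0.31) were higher ventrally and Atp1b2 (0.36) dorsally. Id2 (0.48) of the Wnt and BMP list (adjusted p = 0.56) and Fgf2 (0.345) of the neurotrophic factor list (adjusted p = 0.074) also passed only when adjusted over the list alone. The list calls changed with the replicates left out. Without replicate 1, the synapse-regulating (adjusted p = 0.22) and transporter (0.24) lists were lost. Without replicate 2, the precursor (0.11) and synapse-regulating (0.13) lists were lost, and the astrocyte marker (0.0014), endothelial (0.00020) and mural (0.049) lists were called lower dorsally. Without replicate 3, the transporter (0.49) and Hox (0.31) lists were lost, and the immediate early list (0.0021) was called higher. Signs differed for the dorsal patterning list (median -0.06, mean 0.09, test up, adjusted p = 0.56), the ephrin list (median -0.03, mean 0.01, test up, adjusted p = 0.94) and the mural list (median 0.01, mean -0.09, camera up, adjusted p = 0.95, fry down).

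The overlap of the regional comparisons asked whether genes regional in astrocytes were the genes regional in the other cells. No probe set was called dorsally in both populations, with limma counts of 38 and 5. On the ventral side, 5 probe sets were called in both, of 59 and 9, where 0.019 were expected by chance (one-sided Fisher's exact test, p = 4.0e-12). Dnah12 was the only named one, at -1.49 in astrocytes and -1.49 in non-astrocytes. The p-value treats probe sets as independent, and both comparisons share 1 estimate of the spread per probe set, so it is likely too small. With the replicate number as a block the overlap was 0, since no probe set was then called in non-astrocytes. At an unadjusted p under 0.01 in limma, 60 probe sets went the same way in both, 10 dorsally and 50 ventrally, against 7.70 expected, and 15 went opposite ways. Across all 28467 probe sets, which are not independent replicates, the log2 fold changes had a Pearson r of 0.091 and a Spearman rho of 0.027.

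**Figure D3:**
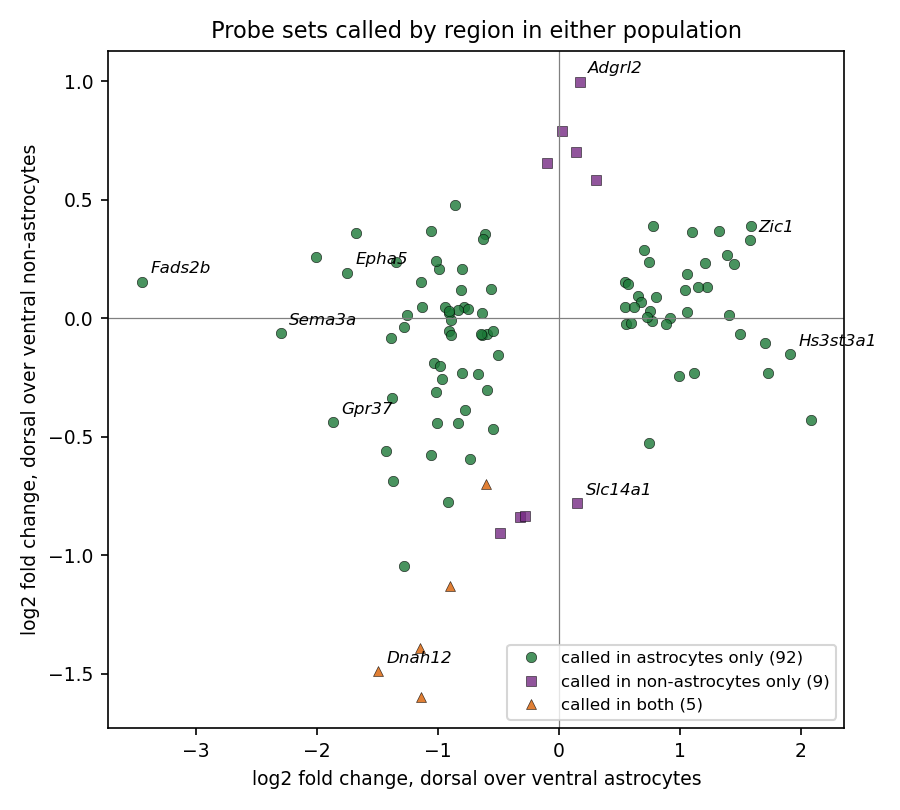
Log2 fold change of dorsal over ventral in astrocytes (horizontal axis) and in non-astrocytes (vertical axis) for the probe sets called in either population. The 5 called in both, Dnah12 among them, lie at the lower left, whereas Sema3a and Epha5 lie far to the left with values of -0.07 and 0.19 in non-astrocytes.

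The interaction asked directly which regional differences differed between astrocytes and non-astrocytes. Sema3a and Epha5 had a ventral excess in astrocytes that was greater than in the other cells, with differences between the log2 fold changes of -2.23 (SE 0.29, adjusted p = 0.025 in limma) and -1.94 (SE 0.19, adjusted p = 0.0065). Hs3st3a1 had a greater dorsal excess in astrocytes than in the other cells, with a difference of 2.06 (SE 0.22, adjusted p = 0.0086). In non-astrocytes, Sema3a had means of 5.64 ± 0.24 dorsally and 5.71 ± 0.08 ventrally, Epha5 6.87 ± 0.17 and 6.68 ± 0.17, and Hs3st3a1 5.09 ± 0.20 and 5.24 ± 0.20 (SD, n = 3 each). The values of Sema3a and Hs3st3a1 there lay under the array medians of 6.57 to 6.62, as did those of Fads2b (3.83 and 3.68). At such low signal a regional difference in non-astrocytes may not show, so these interactions may reflect low expression there.

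Limma called 18 probe sets, 9 in each direction, and 14 of them had names. Toward dorsal astrocytes these were Hs3st3a1, Slc30a10 at 1.56 (SE 0.23), Cyp4f15 at 1.39 (SE 0.22), Dbndd2 at 1.24 (SE 0.20), Unc13c at 1.20 (SE 0.17) and Slc14a1 at 0.93 (SE 0.12). Toward ventral astrocytes they were Fads2b at -3.60 (SE 0.51), Sema3a, Epha5, Nmnat2 at -1.58 (SE 0.20), Gpr158 at -1.33 (SE 0.20), Scrg1 at -1.24 (SE 0.19), Nell2 at -0.96 (SE 0.15) and Dmd at -0.96 (SE 0.15). Nmnat2 encodes an enzyme of NAD synthesis that preserves axons, and Dmd encodes dystrophin. Slc14a1 entered through the non-astrocytes, where it was lower dorsally (-0.78), while in astrocytes it stood at 0.15. Zic1 (1.25, SE 0.23, adjusted p = 0.11) and Pax3 (0.96, SE 0.25, adjusted p = 0.35) did not pass. Aldh1l1, Gfap, Aqp4, Slc1a3 and Kcnj10 did not pass either, with values from -0.18 for Slc1a3 to 0.40 for Aqp4.

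With the replicate number as a block limma called 12 probe sets, 10 of them among the 18. Slc30a10, Cyp4f15, Dbndd2, Gpr158, Scrg1 and Nell2 then lost their calls (adjusted p 0.057 to 0.10). Epha5 and Hs3st3a1 were called whichever of the 12 arrays was left out. Nmnat2 lost its call without ventral astrocytes 2 or ventral non-astrocytes 1 or 3 (adjusted p up to 0.060), and Sema3a without any 1 of 7 arrays, which were dorsal astrocytes 1, ventral astrocytes 2 and 3, dorsal non-astrocytes 1 and ventral non-astrocytes 1, 2 and 3 (adjusted p up to 0.097). Slc14a1 was lost without any 1 of 8 arrays, Slc30a10 and Unc13c of 10, and the remaining 7 genes of 11 (adjusted p up to 0.19 for Cyp4f15). The count of 18 was 6 without dorsal astrocytes 1 or 2, 2 without ventral astrocytes 2, 3 without ventral astrocytes 3, 5 without dorsal non-astrocytes 1, 4 without ventral non-astrocytes 1 or 2, 7 without dorsal non-astrocytes 2 and 2 without ventral non-astrocytes 3, and it was 3 when the leading block of probe sets was tested too.

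Camera called 5 lists for the interaction, and 0 of 19 with an estimated correlation (2 at an unadjusted p under 0.05). Oligodendrocyte precursor markers had lower dorsal over ventral values in astrocytes than in the other cells (median -0.33, adjusted p = 0.0025, and adjusted p = 0.27 with an estimated correlation), with 0 of 9 passing in limma and 3 when adjusted over the list alone, namely C1ql1 (-1.11), Lhfpl3 (-0.80) and Cspg4 (-0.50). Astrocyte synapse-regulating factors pointed the same way (median -0.21, adjusted p = 0.013, and adjusted p = 0.30 with an estimated correlation), with 0 of 14 passing and 4 when adjusted over the list alone, namely Thbs2 (-0.89), Ptx3 (-0.87), Gpc6 (-0.49) and Sparc (-0.48). So did microglia markers (median -0.38, adjusted p = 0.037, and adjusted p = 0.64 with an estimated correlation), with 0 of 13 passing by either count. Dorsal progenitor patterning genes pointed to dorsal astrocytes (median 0.26, adjusted p = 0.037, and adjusted p = 0.27 with an estimated correlation), with 0 of 5 passing and 2, Zic1 and Pax3, when adjusted over the list alone. Astrocyte transporters and channels did too (median 0.25, adjusted p = 0.037, and adjusted p = 0.64 with an estimated correlation), with 1 of 20, Slc14a1, passing and 2 when adjusted over the list alone, the other being Slc13a3 at 0.72. In lists not called or not tested, Nefl (-1.11), Nefm (-0.95), Ret (-0.59), Reln (-1.42), Epha7 (-0.58) and Hapln1 (0.97) passed only when adjusted over the list alone. The test fry called 2 lists, those of oligodendrocyte precursors (adjusted p = 0.040) and dorsal patterning (adjusted p = 0.040). Of the 5 lists, that of oligodendrocyte precursors was called whichever replicate was left out. Without replicate 1 the other 4 were lost (adjusted p = 0.098 to 0.19), without replicate 2 the microglia list (0.41) and without replicate 3 the transporter list (0.36). Without replicate 3, or above the median signal, the pan-neuronal (adjusted p = 0.015 and 0.024) and ephrin (0.038 and 0.024) lists were called lower. Signs differed for the immediate early list (median 0.15, mean -0.05, test up, adjusted p = 0.89), the extracellular matrix list (median -0.04, mean 0.01, test down, adjusted p = 0.99), the mural list (median -0.02, mean 0.00, test down, adjusted p = 0.99) and the myelin list (median 0.00 and negative, mean 0.00 and positive, camera up and fry down, adjusted p = 0.99).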

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

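Of the tests in this part, those of carried-over cells, of left-over astrocytes and of groupings that part each pair for the interaction were chosen only after the results they bear on were seen, and the list of cilium genes was composed after 4 of its members had been seen among the ventral calls. The results listed first stand out because the regional difference itself differed between astrocytes and non-astrocytes in limma's test of the interaction. They were 18 probe sets. As the astrocyte log2 fold change, dorsal over ventral, minus that of non-astrocytes, Hs3st3a1 had 2.06, Slc30a10 1.56, Cyp4f15 1.39, Dbndd2 1.24, Unc13c 1.20 and Slc14a1 0.93. In the ventral direction, Dmd had -0.96, Nell2 -0.96, Scrg1 -1.24, Gpr158 -1.33, Nmnat2 -1.58, Epha5 -1.94, Sema3a -2.23 and Fads2b -3.60.

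Regrouping the same arrays gave a measure of chance. For the interaction, 2 of 100 groupings, the real one included, called at least 18 probe sets, and the highest other count was 20, a share under 0.05 for groupings drawn without regard to the replicate numbers. These numbers pair the non-astrocyte arrays, and of the 32 groupings that part all 3 pairs in both populations, 2 called at least 18, and 3 at least the real 12 with the replicate block. The highest of these, 83 (84 with the block), came from the grouping that keeps the astrocyte regions and exchanges those of the non-astrocytes. That grouping adds both regional differences instead of subtracting them, so it is no measure of chance. Of the 31 without it, 1, the real one, called at least 18, and the highest other count was 11. The share falls under 0.05 only without the exchanged grouping, in a test chosen after the results were seen. Chance is therefore left open for this count. With the block 2 of the 31 called at least 12, the highest other count being 12, and chance cannot be excluded there either. For astrocytes against non-astrocytes, 1 of 100, the real one, called 10305, and the highest other count was 17, a share under 0.05. The other groupings mix astrocyte and non-astrocyte arrays within a group. This widens the spread there and lowers their counts, so 17 is no count expected without any difference. For the numbers of lists, 20 of 100 groupings called at least the real 5 of the interaction (highest other 8) and 35 of 100 at least the real 8 of astrocytes against non-astrocytes (highest other 10). A group of 3 drawn from 3 and 3 arrays always holds more of one kind, so these groupings keep part of the differences and give no reference without change for the lists, and chance is left open for their numbers. For the regional comparisons within a population, the 10 splits of 6 arrays are too few for a share under 0.05. In astrocytes the real split called 97 probe sets against 4 in the highest other, and 2 lists against 3, with at least 2 lists in 7 of the splits. In non-astrocytes the real split, which parts all 3 pairs, called 14 against 1 in the highest other, and 6 lists against 5. The 3 other splits that part 3 pairs called 0 probe sets each (1494 at an unadjusted p under 0.05 in limma for the real one), the 6 that part 1 pair at most 1, and with the replicate block limma called 0 for the real split.

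The first pattern weighed is the set of 38 named probe sets called higher in ventral astrocytes. If GFP-negative cells had been carried over into the ventral astrocyte sort, myelin genes would have come along, and the highest share of such cells that any of 13 myelin markers implied was 10.7%, with a median of 3.89%. All 38 called genes, 100%, implied a greater share, with a median of 95.9%. They were called for the ventral excess from which the share is computed, which favours greater shares, so this comparison decides little. Of the 38, 25 stood above the level of the ventral non-astrocytes themselves by more than 2 SE. For these 25, this argues against carry-over of the average GFP-negative cell as the cause, and for the other called genes it stays open. Carry-over of a particular kind of ventral cell, of which the non-astrocyte arrays hold little, could still contribute and was not tested, and a difference between the astrocytes of both regions, the one the design names, stays open as a hypothesis.

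The second pattern is the group of genes higher ventrally in both populations, of which Dnah12 is the one named. A candidate explanation is a greater number of ciliated ependymal cells in the ventral tissue. Of 123 genes of motile cilia, 7 were measured under a name, and 4 of them, Dnah12, Fam216b, Cfap54 and Mns1, were called in ventral astrocytes (-1.49, -1.28, -1.06 and -0.78), while in non-astrocytes Dnah12 was called (-1.49) and Fam216b (-1.05), Cfap54 (-0.58) and Mns1 (-0.39) were higher ventrally without passing. The 3 not called in either population had a median of -0.01 in astrocytes, at the 50.2 percentile of random lists, and of -0.12 in non-astrocytes, at the 12.9 percentile, which is too few genes to decide, and Rarres2, the one measured ependymal marker, stood at -0.23 in astrocytes and 0.03 in non-astrocytes. Whether the GFP gate removes or keeps such cells is not given in the sources used here, and with the replicate block none of these genes was called in non-astrocytes, nor Cfap54 and Mns1 in astrocytes (adjusted p = 0.051 and 0.078), so ependymal cells and a regional difference within both populations cannot be told apart.

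The third pattern is Slc14a1, higher in ventral than in dorsal non-astrocytes (-0.78). Since the gene is 1 of the astrocyte transporters listed, astrocytes left in the ventral GFP-negative sort could explain it, at an added share of 3.58%. That share predicts that 19 astrocyte markers rise ventrally by a median of 0.45 on the log2 scale. Their observed median was 0.0122, with 11 of 19 higher ventrally and 18 of 19 under their prediction. The SE of that median, 0.084, comes from the scatter across the 19 markers and does not measure the spread between arrays. Some markers with large predicted rises rose in part, with Mlc1 at 0.64 (predicted 0.95), Gfap at 0.52 (0.86), Gja1 at 0.51 (0.66), Slc4a4 at 0.50 (1.22) and Aqp4 at 0.35 (1.24), and Kcnj10 rose by 0.31, above its 0.19, whereas Slc1a3 stood at 0.03 (0.60), Gjb6 at -0.11 (0.66), Slc1a2 at -0.17 (0.66) and Atp1b2 at -0.36 (0.38). Over the markers as a set this argues against left-over astrocytes of average composition, at that share, as the whole cause. The spread between arrays was not taken into account, and a smaller share stays open. A ventral kind of astrocyte rich in Slc14a1 was not tested, a regional difference in the other cells stays open, and the call itself was lost with the replicate block (adjusted p = 0.072 in limma, with 0.0056 to 0.42 over the alternatives).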

How the results depend on the processing

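Fits limited to named genes, and fits of 1 population with the block, were chosen after seeing the data; the other alternatives were planned. No named gene that was called changed sign under any alternative. Of the named genes not called, Aqp4 (-0.036 to 0.092) and Kcnj10 (-0.069 to 0.079) in astrocytes by region, Sema3a (-0.17 to 0.072) and Slc1a3 (-0.073 to 0.017) in non-astrocytes, and Gfap in the interaction (-0.46 to 0.43) had both signs over the alternatives. Over genes and alternatives, 2858 values for astrocytes against non-astrocytes kept their side of the threshold and 42 lost a call; these numbers were 455 and 88 for dorsal against ventral astrocytes, 174 and 88 for the same comparison in non-astrocytes, and 297 and 193 for the interaction. With the replicate number as a block, limma called 108 probe sets in astrocytes by region (97 without), 10551 between the populations, 12 for the interaction and 0 for region in non-astrocytes (1716 at an unadjusted p under 0.05); the overlap of the regions was then 0, as nothing was called in non-astrocytes. The block changed no count of lists. It ended the calls of the 6 named genes in non-astrocytes and of Cyp4f15, Dbndd2, Gpr158, Nell2, Scrg1 and Slc30a10 in the interaction (adjusted p 0.057 to 0.10). In astrocytes by region, 56 of 62 called probe sets with names were still called, and Brinp2, Cfap54, Fkbp1b, Ildr2, Mns1 and Tmprss11d were not (adjusted p 0.051 to 0.080); between the populations 5097 of 5098 were. The lowest same-number correlation of deviations in any pair of groups was 0.039, between dorsal astrocytes and dorsal non-astrocytes, under the highest of other numbers there, 0.056. In the other pairs of groups, every same-number correlation lay above all those of other numbers. In the order dorsal against ventral astrocytes, the same in non-astrocytes, and interaction, testing every probe set with the leading block gave 46, 0 (1698 at an unadjusted p under 0.05) and 3, and an adjusted p of 0.01 gave 30, 0 (1494) and 2. At least 2-fold differences numbered 44 in astrocytes by region, 4 in non-astrocytes and 1780 between the populations. Array weights, lower for every astrocyte array than for any non-astrocyte array, gave 35 and 43 by region. With the arrays of a population fitted alone, there were 27 and 1, and with the block added 37 and 0 (2750 at an unadjusted p under 0.05). The mean of the probe sets of each named gene gave 4567 between the populations and 3 for region in non-astrocytes, and named genes only gave 4567 and 6. Only 4575 genes were tested there. Nearly all were named because the authors listed them for astrocytes against non-astrocytes, so the 4567 follow largely from the naming. Leaving out arrays gave 8 to 100 for region in astrocytes, 7664 to 10403 between the populations, 0 to 31 for region in non-astrocytes (0 in limma being 1254 to 1363 at an unadjusted p under 0.05 without a ventral array) and 1 to 14 for the interaction. For lists the ranges were 2 to 5, 7 to 8, 4 to 7 and 1 to 6. With an estimated correlation camera called 0 lists in each of the 4 comparisons (1, 4, 1 and 2 at an unadjusted p under 0.05, in the order astrocytes by region, populations, non-astrocytes by region, interaction), and fry called 1, 17, 0 (4) and 2. Above the median signal, camera called 6 lists in astrocytes by region. At an unadjusted p under 0.01, 60 probe sets were shared by the regions. Apart from thresholds and fewer genes or arrays, the cause was not tested. On simulated data with independent noise, equally wide in all groups, a change of 0.5 on the log2 scale was recovered in 46% of cases. Smaller regional differences were therefore often not detectable with 3 arrays per group.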

Other observations

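Further called genes, named after their values were seen, differed by region in the sorted astrocytes. Sulf2, which encodes a sulfatase that trims heparan sulfate, was higher ventrally at -1.13 (adjusted p = 0.010 in limma). Itih5, which encodes a hyaluronan-binding protein, stood at -1.14, and P3h2, a collagen-modifying enzyme gene, at -0.94, both higher ventrally. Aldh1a1, which encodes an enzyme that makes retinoic acid, was higher ventrally at -0.83 (adjusted p = 0.029), and Pmepa1, a target and inhibitor of TGF-beta signalling, at -0.99 (adjusted p = 0.0022). Ventral astrocytes also had more signal for Nmnat2 at -1.34, Scrg1 at -1.28, Plcb1, a phospholipase gene, at -0.91, and Hpgd, which encodes a prostaglandin-degrading enzyme, at -1.02. In every gene of this paragraph, as in all 97 called probe sets, all 3 arrays of one region stood above all 3 of the other. Sulf2 and Plcb1 stood no higher in ventral astrocytes (8.65 and 8.34) than in ventral non-astrocytes (9.91 and 8.40). Scrg1 (10.41 against 10.22) and Pmepa1 (8.85 against 8.64) were higher there by less than 2 SE. For Sulf2, Plcb1, Scrg1 and Pmepa1, carry-over of GFP-negative cells therefore stays open.

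On the dorsal side, the atypical cadherin gene Fat4 stood at 1.10 (adjusted p = 0.0053 in limma), Il17rd, which encodes an inhibitor of fibroblast growth factor signalling, at 1.06, called by 2 probe sets, and Enpep, an aminopeptidase gene, at 1.12. Gabbr2, a subunit of the GABA-B receptor, was higher dorsally at 0.77 (adjusted p = 0.020), the phosphodiesterase gene Pde8a at 0.92 and the glycosylation gene Galnt14 at 0.74. These genes were picked singly. The extracellular matrix list fixed beforehand was not called in this comparison (adjusted p = 0.61, mean 0.12), and its 1 called member of 13, Hapln1, was higher dorsally.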
